A study of Mus musculus with 3 samples.

How the data were processed

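Poly(A) RNA of N1E-115 cells was measured by RNA-seq in 3 libraries, labelled as untreated cells at day 0. Per the labels' protocols, RNA was extracted with ISOGEN, poly(A) RNA was isolated on magnetic beads, and libraries were made with a directional kit. The submitters' processing notes name STAR as a tool and mm10 as the genome build, without a version or role. The counting tool, its annotation and its strand setting are not given in the sources used here, so reads of overlapping or antisense genes may not be separable. The deposited table holds estimated counts per gene symbol, not scaled for depth. Most values were whole within a tolerance of 0.01; between 1.76 and 1.98% of values per library were fractional, in 578 genes, as when reads shared by similar genes are divided. Counts were rounded to whole numbers before use.

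The table had 24411 rows. Of these, 27 carried calendar dates in place of gene symbols and were left out of totals and tests; they held 0.306, 0.295 and 0.281% of the counts of replicates 1, 2 and 3. No mitochondrially encoded gene (prefix mt-) was listed. The remaining 24384 named genes gave the library totals. Gene positions, exon lengths and GC content came from the GENCODE annotation of the same build (mm10), to which 23975 genes (98.3%) were matched, 666 of them through older symbols. The older symbols and both aliases needed for the gene lists (Scn2a1 and Car9) were taken from RefSeq gene synonyms.

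CPM was the count divided by the library total of named genes. A gene was called detected at a CPM of at least 1 in every library. The precision is set by the depth of 13942014 to 17731376 counts: a count of 0 allows up to 3 counts, and ratios of summed counts carry exact (Clopper-Pearson) 95% intervals, for counting error only. Gene pairs and list contrasts used log2(CPM + 0.1); a ratio to a gene or list median at 0 is then set by the pseudocount, and can exceed the one against the 3-count floor. For a list contrast, the difference of the list medians was taken per library and the members were permuted between the lists (100000 resamples, two-sided), with Benjamini-Hochberg adjustment over 8 contrasts. Genes are not independent replicates, and 3 libraries cannot go below a two-sided exact sign-flip p of 0.25. The 31 gene lists, the 8 contrasts, the 8 gene pairs and the tests were fixed before the data were examined, as were most alternatives; the closing section names those added later.

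Variation between replicates was tested with edgeR 4.0.16 in R 4.3.3: an intercept-only negative binomial fit with TMM normalization, the filterByExpr filter and trended dispersion, with the deviance of each gene compared with a chi-square distribution of 2 degrees of freedom. On simulated counts for 11821 genes with no gene changed, 0 genes were called. The simulated counts followed the fitted dispersion trend exactly, without spread of single genes around it and without a trend on exon length. They therefore do not show how many calls in the data come from these sources. With 200 genes lowered in 1 library, 6.5% were recovered at 1.5-fold, 54% at 2-fold and 88% at 4-fold. In 200 random pairs of lists of 15 detected genes, 6% gave a permutation p under 0.05; lists with undetected members were not simulated. List shifts in a library were the median log2 ratio of its TMM-scaled CPM to the mean of the other libraries over detected members, ranked among 10000 random lists of the same size matched on mean expression. Python 3.11.15, SciPy 1.17.1 and pandas 2.3.3 were used for the rest. DESeq2 1.42.0 served for alternative size factors.

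Genes named in the text are the 20 with the highest mean CPM, the 20 highest after leaving out mitochondrial, ribosomal protein and reference genes, the 5 highest members of each list and its first 3 undetected members, both genes of each pair, the 10 with the smallest p in the test of variation, and further members of a list where the list is described. Alternatives covered the detection minimum, the library scaling, the low-count filter, the dispersion, the pseudocount, detected members only, counts per kilobase of exon, the mean in place of the median, and leaving out each replicate. No between-group comparison was made because there was 1 group. Some fixed genes, 2 of the gene pairs and 1 gene list are not reported here.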

Results

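Poly(A) RNA of N1E-115 cells was sequenced in 3 libraries, all from untreated cells at day 0. N1E-115 is a mouse cell line derived from a neuroblastoma, a tumour of the sympathetic nervous system lineage, and is used as a model of adrenergic neurons. The labels give a single group, so there was no comparison between conditions, and the data describe which genes the line expressed and how closely the replicates matched. The libraries held 17731376, 13942014 and 15432235 estimated counts in named genes (replicates 1, 2 and 3). Levels are counts scaled to these totals (CPM), given as mean ± SD over n = 3 libraries unless stated otherwise. One count was worth between 0.0564 and 0.0717 CPM, and a gene without counts had an upper limit of 3 counts, or between 0.169 and 0.215 CPM per library. Intervals and limits cover counting error only.

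Of 24384 named genes, 11522 had at least 1 CPM in every library and are called detected. Single libraries held 11829, 11855 and 11691 such genes (mean 11792 ± 88.1). At least 100 CPM was reached in every library by 2250 genes, and 8938 genes had no counts in any library. Eef1a1, the translation elongation factor, had the highest CPM at 8468 ± 676, followed by the chaperone Hsp90ab1 (5853 ± 601), the elongation factor Eef2 (3713 ± 286) and Actb (3525 ± 264). Map1b, a microtubule-associated protein of growing axons, was the fifth at 3492 ± 761 CPM. CPM is not scaled for transcript length, which favours long genes in this order: Map1b has 15846 nt of exon, against 1462 nt for Ptma. Further genes of the neuronal or neuroendocrine lineage stood near the top: Chgb, a chromogranin of secretory granules (2632 ± 197), Dpysl3, a growth-cone protein (2269 ± 158), and Ret, the receptor tyrosine kinase for GDNF-family ligands (1899 ± 181). The other genes with high counts were largely housekeeping genes, among them Hsp90aa1 (3075 ± 275), Hspa8 (2992 ± 379), Ptma (2851 ± 333) and Atp5b (2842 ± 129). The tubulin gene Tuba1a was at 2522 ± 109 CPM. Rn45s, the ribosomal RNA precursor, was at 2079 ± 423 CPM. Ribosomal protein genes took 6.22 ± 0.56% of counts, and the 14 common reference genes were all detected, with a median of 1077 CPM.

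**Figure D1:**
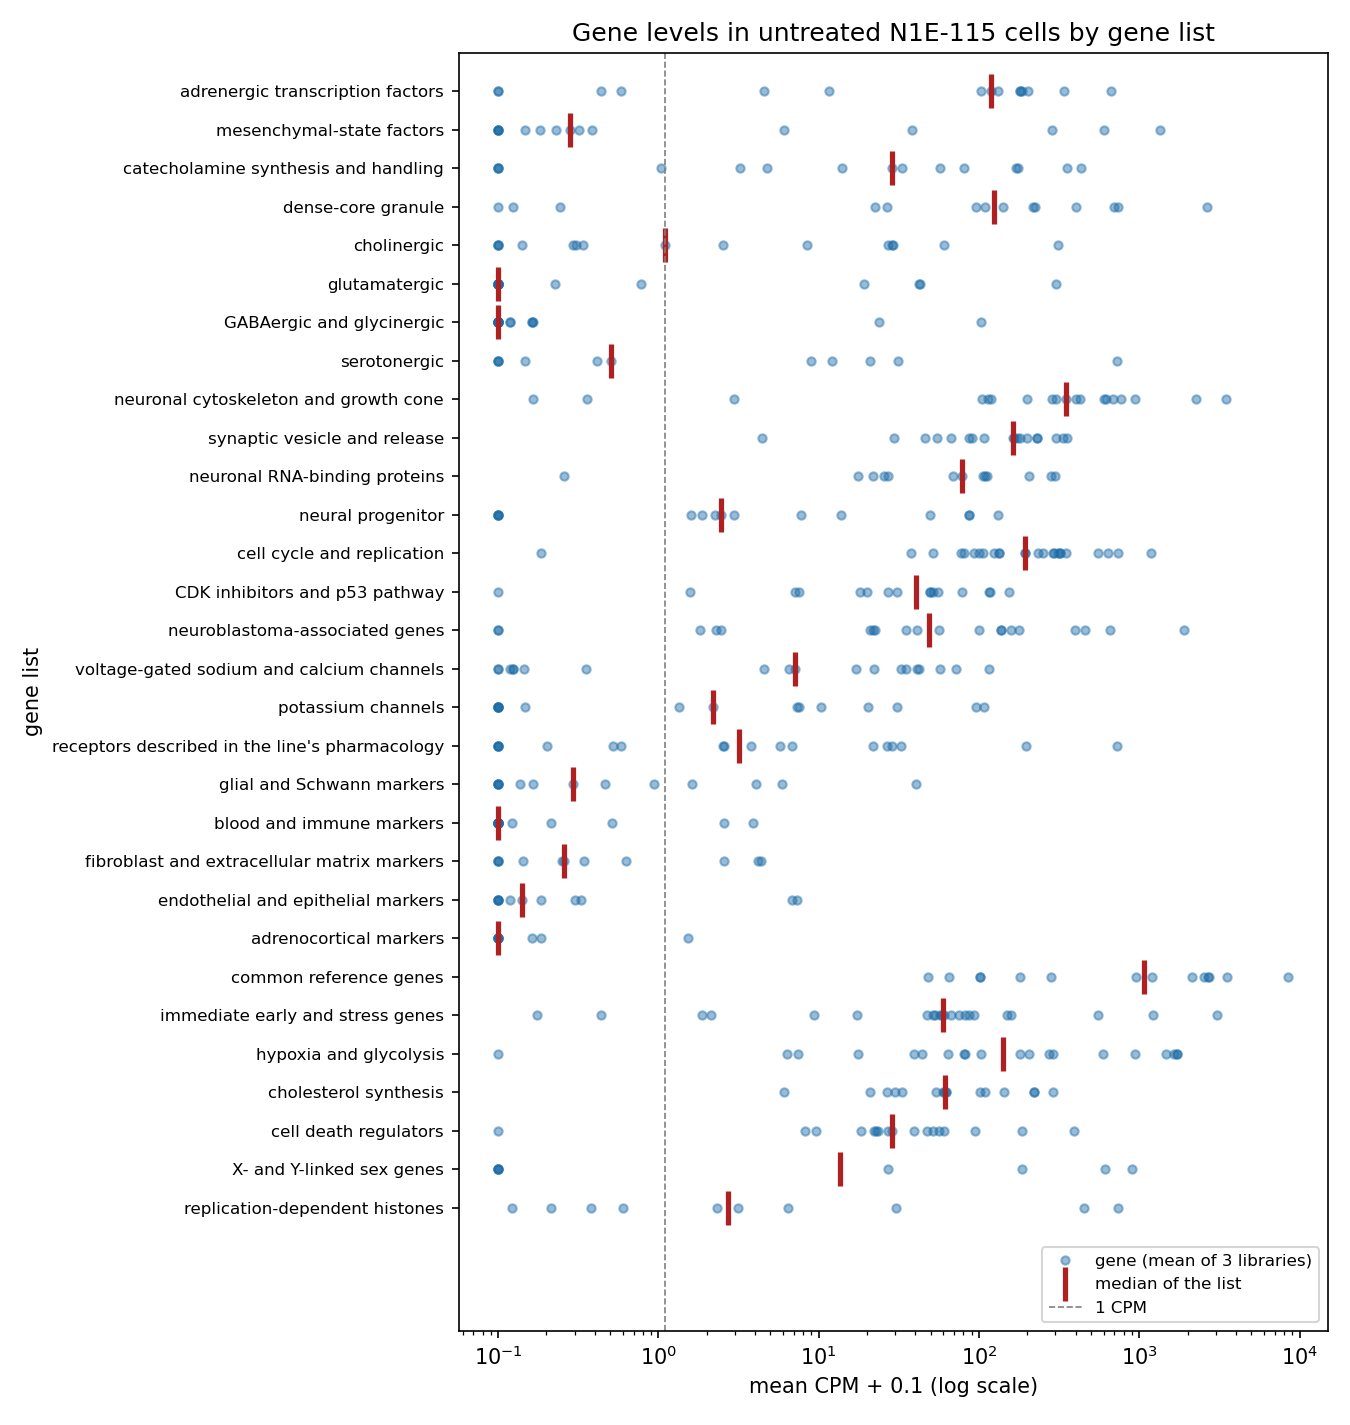
Mean CPM plus 0.1 of every member of 30 gene lists (log axis); each point is a gene, the red bar is the median of the list and the dashed line marks 1 CPM. Medians of the cytoskeleton (349 CPM) and cell cycle (194 CPM) lists lie far above those of the glial (0.192 CPM) and immune (0 CPM) lists.

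The transcription factors of the sympathoadrenal lineage were mostly expressed. Of the 15 listed, 11 were detected, 9 of them at 100 CPM or more, with a list median of 118 CPM. Hand2 was the highest (670 ± 62.0 CPM; chromosome 8, 57320983 to 57324633 in mm10), followed by Insm1 (340 ± 15.8), Phox2a (201 ± 25.0) and Tbx2 (185 ± 26.4). Gata2, Isl1 and Gata3 reached 180, 118 and 102 CPM. Tlx2 had no counts in any library, and Hand1 (0.483 CPM) and Eya1 (0.336 CPM) were not detected. Factors of the mesenchymal state of neuroblastoma were detected in 5 of 15 cases, with a list median of 0.180 CPM. Twist1, Twist2, Fosl1 and Yap1 had no counts. Vim (1350 ± 110 CPM), Fn1 (602 ± 301) and Tcf4 (286 ± 19.8) were nevertheless high. The adrenergic list exceeded the mesenchymal list by 8.84 ± 0.70 in log2(CPM + 0.1) medians, in 3 of 3 libraries, and by 8.97 ± 0.37 with values under 3 counts raised to that floor. This did not pass the threshold (two-sided permutation test over list members, Benjamini-Hochberg adjusted p = 0.0512 over 8 list contrasts), and the adjusted p was 0.0415 without replicate 1 and 0.0426 without replicate 2. Among detected members alone the difference turned to -0.74, and over the alternatives fixed beforehand the permutation adjusted p ranged from 0.0261 to 0.499.

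The line expressed the genes of noradrenaline synthesis and storage. Dbh, which makes noradrenaline from dopamine, was at 430 ± 46.5 CPM, Gch1, which supplies the cofactor of tyrosine hydroxylase, at 354 ± 63.0, Th, the rate-limiting enzyme, at 174 ± 27.7, and Slc18a2, the vesicular monoamine transporter, at 171 ± 27.3. Ddc, the decarboxylase between Th and Dbh, was only 3.13 ± 0.55 CPM. Pnmt, which makes adrenaline, had no counts, nor had Slc6a3 and Maob, and Slc6a2, the noradrenaline transporter, was not detected (0.944 CPM). In all, 11 of 15 genes of catecholamine synthesis and handling were detected. Of the 2 vesicular transporters, Slc18a1 was lower than Slc18a2 (mean log2 ratio -5.26 ± 0.47). Of the genes of secretory granules, 11 of 14 were detected, with Chgb first and Scg2 (736 ± 8.62), Vgf (699 ± 51.3), Chga (403 ± 27.2) and Ptprn (223 ± 49.7) after it, whereas Pcsk1 had no counts and Npy 0.0239 CPM.

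Smaller shares of the listed genes of other transmitters were detected, although some of these genes were abundant. Among cholinergic genes 7 of 15 were detected. Chrna3, a nicotinic receptor subunit of autonomic neurons, was high (313 ± 53.3 CPM), followed by Chrnb2 (60.2), Chrna7 (28.9), Chrm4 (28.7) and the acetylcholine-degrading enzyme Ache (27.1). Chat, which makes acetylcholine, held 12 counts over the 3 libraries against 8222 for Th, a 685-fold ratio (95% exact interval 392 to 1327), and Slc5a7 and Chrm5 had none. Glutamatergic genes were detected in 4 of 14 cases (among them Grin1 42.9, Grik5 42.4 and Gria2 18.9 CPM). GABAergic and glycinergic genes were detected in 2 of 15 cases (Gabbr1 23.6 CPM), and Gad2 had no counts. Serotonergic genes were detected in 5 of 11. Htr3a, the serotonin-gated channel, was at 721 ± 105 CPM, above the muscarinic receptor Chrm1 by a mean log2 ratio of 8.15 ± 0.36. Tph2, Fev and Tph1 were at 20.8, 12.0 and 8.87 CPM. The catecholamine list exceeded the GABAergic list by at least 148-fold in its median with values under 3 counts raised to that floor (log2(CPM + 0.1) difference 8.16 ± 0.11, permutation adjusted p = 0.0186). Among detected members alone the difference was 0.17, with a permutation adjusted p of 0.950, the highest of a range from 0.00256 over the alternatives. The differences to the glutamatergic list (8.16 ± 0.11, adjusted p = 0.0570; 7.21 with the floor, since its median was also 0) and the cholinergic list (4.80 ± 0.72, adjusted p = 0.113) did not pass the permutation test, and were 0.37 and 0.98 among detected members alone. The serotonergic list was not tested against it.

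**Figure D2:**
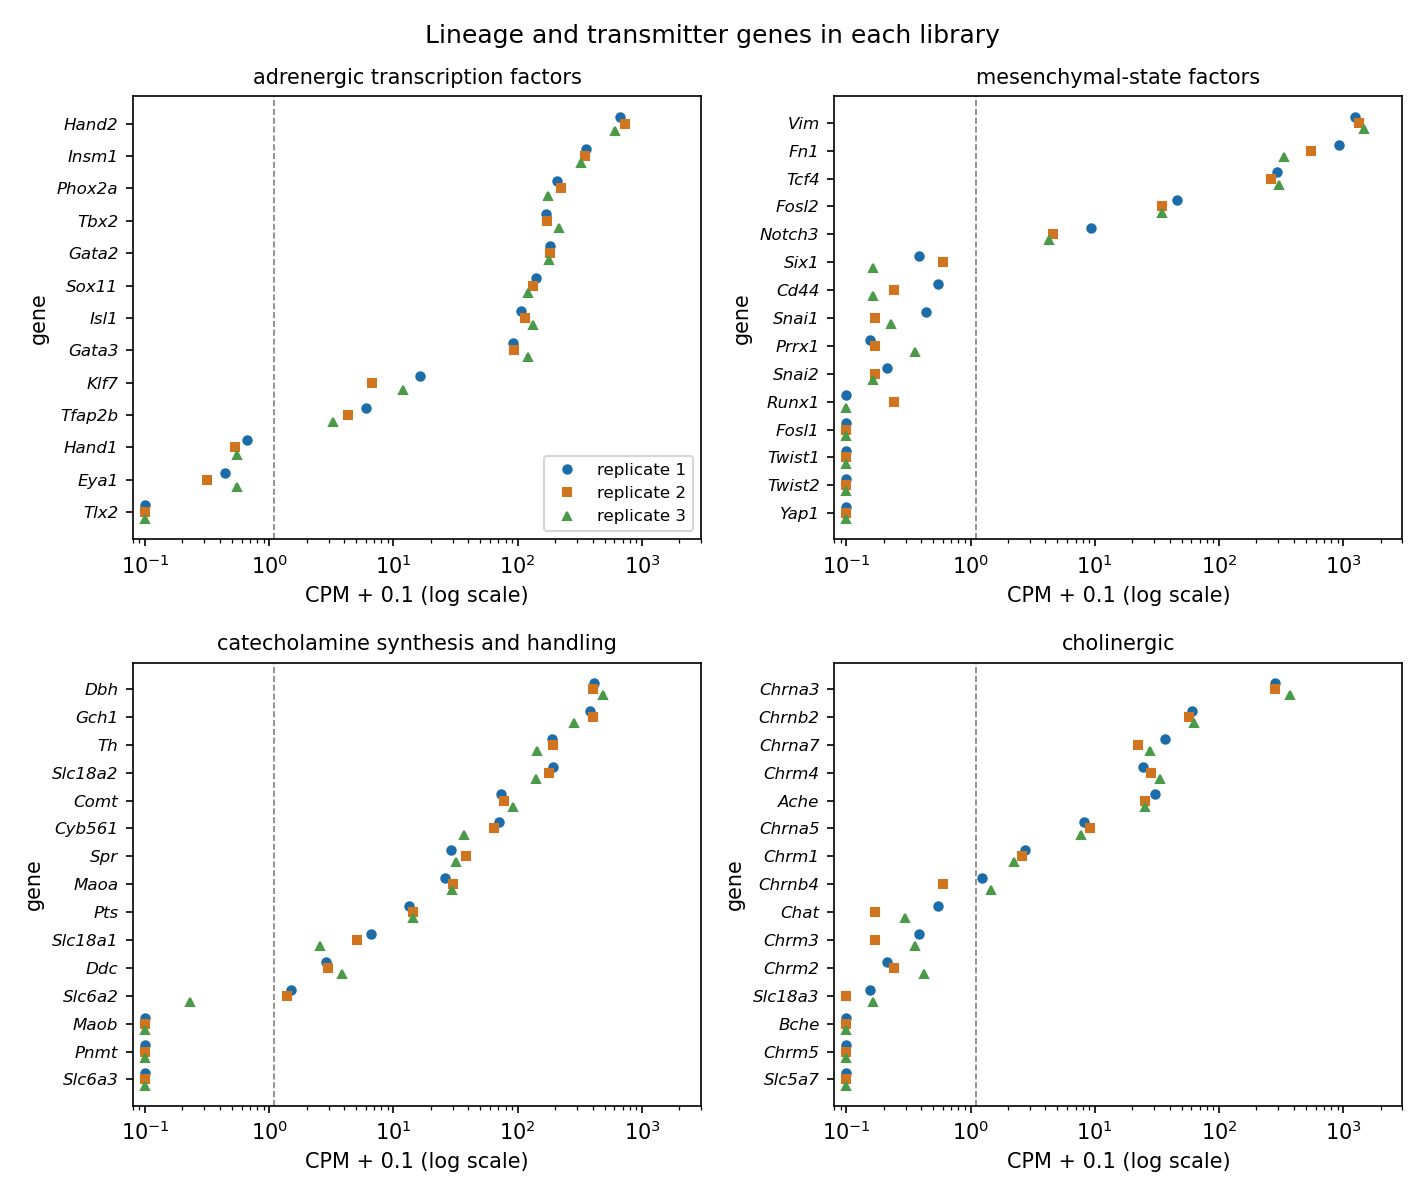
CPM plus 0.1 of genes of 4 lists in each of the 3 libraries (log axis); symbols mark the replicates and the dashed line marks 1 CPM. Hand2 lies near 670 CPM and Dbh near 430 CPM in every library, whereas Twist1, Pnmt and Slc5a7 had no counts.

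The neuronal cytoskeleton and growth-cone genes were detected in 17 of 19 cases, with a median of 349 CPM. After Map1b and Dpysl3 came the intermediate filament gene Prph (934 ± 55.8 CPM), Uchl1 (771 ± 39.9) and Tubb3 (689 ± 42.0), and Gap43 was at 600 ± 46.9 CPM. Nefh was at 428 ± 35.4 CPM, but Nefl and Nefm were not detected (0.0648 and 0.259 CPM). Dcx was low, at 2.87 CPM. All 18 genes of synaptic vesicle release were detected (median 164 CPM), led by Syn2 (352), Cplx1 (335), Syp (301), Syt4 (230) and Syt1 (229). Neuronal RNA-binding proteins were detected in 12 of 13 cases, among them Rbfox2 (299), Elavl4 (281), Celf3 (204), Elavl3 (112) and Elavl2 (109). Rbfox3, the gene of the NeuN antigen of mature neurons, held 7 counts against 13239 for Elavl4. Neural progenitor genes were low, with 11 of 15 detected and a median of 2.37 CPM; Id1 was at 130 and Nes at 86.9 CPM, and Sox1, Sox2, Sox3 and Fabp7 had no counts. The cytoskeleton list exceeded the progenitor list by 7.19 ± 0.13 (log2 medians, higher in 3 of 3 libraries, permutation adjusted p = 0.00024). Its excess over the synaptic list, 1.26 ± 0.20, did not pass (adjusted p = 0.0570).

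Cell cycle genes were abundant. Of 25 listed, 24 were detected, with a median of 194 CPM: Top2a 1180 ± 75.8, Ccnd1 739 ± 24.2, Mki67 641 ± 93.9, Ccnb1 549 ± 50.6 and Mcm2 349 ± 12.2. Cdk6 held 4 counts against 13845 for Cdk4, a 3461-fold ratio (95% exact interval 1352 to 12705). Inhibitors of cyclin-dependent kinases and p53 pathway genes were lower, with 14 of 16 detected and a median of 40.2 CPM. Trp53 was at 154, Mdm2 at 117 and Cdkn1b at 115 CPM, Cdkn2a was at 51.7 CPM, and Cdkn2b had no counts. The cell cycle list exceeded the inhibitor list by 2.38 ± 0.18 in log2, in 3 of 3 libraries (permutation adjusted p = 0.00024). Of the 10 histone genes, 6 were detected, with a list median of 2.63 CPM. The highest were H1f0 (734) and H2afz (449), variants also made outside replication, and H2afx (30.1). The libraries were made from poly(A) RNA, so histone transcripts without a poly(A) tail were not measured. The low levels of the other histone genes are therefore no measure of their expression in the cells.

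Of 20 genes associated with neuroblastoma, 18 were detected. Ret was followed by Odc1 (661 ± 47.1 CPM), the neurotrophin receptor Ngfr (457 ± 59.2), Kif1b (400) and Atrx (178). Mycn (138 ± 18.7) and Myc (158 ± 1.67) were close, with a mean log2 ratio of -0.21 ± 0.20, and Lmo1 (137) and Lin28a (99.3) were also high. Ntrk2 and Gfra3 had no counts. Among sodium and calcium channel genes, 12 of 19 were detected, led by Cacna1h (115), Scn3b (71.6), Scn3a (57.2), Cacna1c (42.1) and Cacna1b (41.0). Potassium channel genes were detected in 9 of 15 cases, among them Kcnh2 (95.4), and the difference between these lists did not pass (1.68 ± 0.29, permutation adjusted p = 0.490). Of 18 receptors known from the pharmacology of the line, 11 were detected, including Cnr1 (196), P2rx7 (32.5), S1pr2 (26.6) and Oprd1 (21.8).

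Markers of other cell types were low. The highest members were Cnp for glia (40.3 CPM, 4 of 13 detected), Vwf for endothelium and epithelium (7.26, 2 of 11), Pdgfra for fibroblasts (4.24, 3 of 11), Cd74 for blood and immune cells (3.80, 2 of 13) and Star for the adrenal cortex (1.43, 1 of 8). Xist, the RNA that coats an inactive X chromosome, was at 897 ± 207 CPM. The 4 listed Y-linked genes, Ddx3y, Eif2s3y, Kdm5d and Uty, had no counts. Immediate early and stress genes were detected in 20 of 22 cases, led by Hsp90aa1, Hspa5 (1217 ± 44.9) and Atf4 (554 ± 45.5), and Fos was at 17.3 CPM. All 16 genes of cholesterol synthesis were detected (median 61.0 CPM), among them Hmgcs1 (221) and Srebf2 (219). Cell death regulators were detected in 16 of 17 cases, with Cycs (394) and Mcl1 (184) the highest and Pmaip1 without counts.

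Replicates resembled each other closely, and 76 of 11821 tested genes varied between them more than genes of similar count (edgeR negative binomial deviance test, trended dispersion, Benjamini-Hochberg adjusted p under 0.05). The median coefficient of variation of detected genes was 9.80%, and the common biological coefficient of variation was 11.6%. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 12.5 to 17.3), so none was treated as a duplicate of another. Nothing in the labels says whether they were separate cultures, so the spread, and the p-values that rest on it, may be technical. Ndrg1, a hypoxia-inducible gene, came first with 1060, 641 and 177 counts (edgeR adjusted p = 1.3e-14). The next were Gm5643 (61, 31 and 289 counts), Cntnap2 (233, 164 and 20), Sptb (209, 83 and 13), Ndufs5 (16, 100 and 138), Fn1 (16435, 7613 and 5146), Cbl (1000, 238 and 512), Txnip (922, 606 and 260), Acat3 (41, 138 and 25) and Npcd (279, 620 and 283). Gm5643, Ndufs5, Acat3 and Npcd had fractional counts, so reads shared with other genes make their levels uncertain. Replicate 3 was the lowest for 43 of the 76 genes and replicate 2 for 27, and replicate 1 was the highest for 55. The genes lowest in replicate 2 were long, with a median exon length of 11538 nt against 4549 nt for all tested genes and 3350 nt for those lowest in replicate 3. Fewer genes were called with fewer libraries, 36 without replicate 1, 40 without replicate 2 and 52 without replicate 3.

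Gene lists also moved together in single libraries. Of 81 combinations of list and library, 21 had a median outside the central 95% of 10000 random lists matched on expression. For members that vary independently, 4.05 are expected by chance. Members of a list can vary together, and the values of a list in the 3 libraries depend on each other, so the excess is descriptive. The hypoxia and glycolysis genes, detected in 19 of 20 cases and abundant (Eno1 1730, Ldha 1715, Pkm 1656, Aldoa 1464 and Tpi1 937 CPM), were lower in replicate 3 in 19 of 19 detected members. Their median log2 difference from the other libraries was -0.37, below all 10000 random lists, and in replicate 1 it was 0.33. Cholesterol synthesis genes were also lower in replicate 3 (-0.24, 13 of 16 members), as were immediate early and stress genes (-0.23, 15 of 20). The highest member of the latter list, Hsp90aa1, was higher there (3391 CPM against 2886 and 2950 in replicates 1 and 2). Hsp90 and Hsp70 genes together also took more of its counts (1.79% against 1.54 and 1.59%). The difference of the immediate early and stress list was -0.15 over the 19 members with a known length. It was -0.11 over the same members after a trend on exon length and GC content was removed. Sodium and calcium channel genes were higher in replicate 1 (0.49, 11 of 12), by 0.28 (10 of 12) after removal of that trend. Rn45s also differed in replicate 3, where it took 0.159% of counts against 0.233 and 0.232% in replicates 1 and 2. These values compare 1 library with the others of its group and carry no test of a condition.

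**Figure D3:**
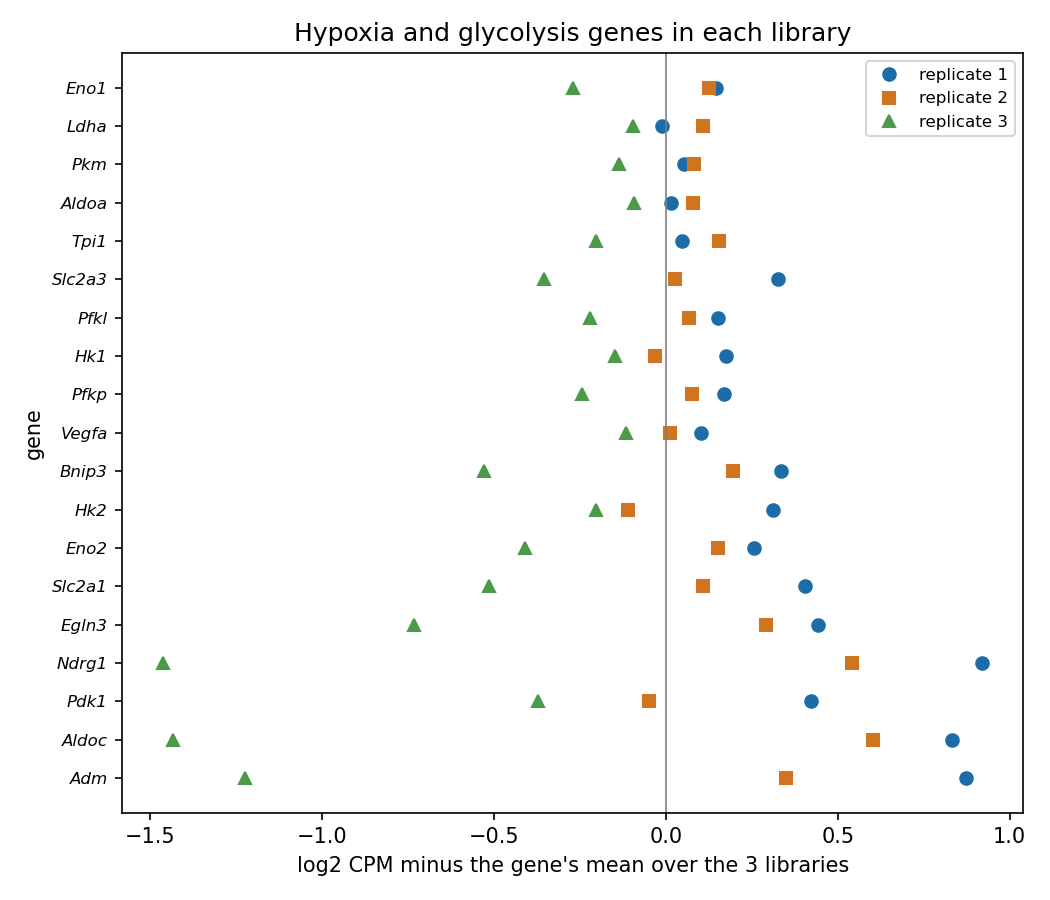
log2 CPM of each detected hypoxia and glycolysis gene minus its mean over the 3 libraries; symbols mark the replicates. Replicate 3 is the lowest for every gene shown, from -0.09 for Aldoa to -1.46 for Ndrg1.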

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

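Tests written after the result was seen were those of the length and GC trend, the separate hypoxia list, GC content, RNA fragments and both tests of shared reads; those of the amino acid list, depth and gene body length were written before. Dixon's test was not run, since the group had only 3 samples.

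The 27 rows named by calendar dates were the data outside the measurement. They held 139034 estimated counts over the 3 libraries (54360, 41180 and 43495), far above the limit that a count of 0 allows. Spreadsheet software turns symbols such as those of the septin and March families into dates, so these genes' levels are not reported.

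The hypoxia and glycolysis genes were lower in replicate 3. A trend on exon length and GC content does not account for this as a whole: after its removal the list median was -0.45 with 18 of 18 members lower, below all 10000 random lists. Over the 18 members with a known length it was -0.44 before removal, so the trend changed it little. Lower hypoxia-inducible transcription in that culture is a candidate explanation, and a separate list of hypoxia-inducible genes was also lower there (median log2 -0.19, 15 of 18 members lower). Amino acid response genes were lower by much less (-0.051, 14 of 19 members, at the 1.30 percentile of random lists). By then the immediate early and stress list had already been seen lower there. A broader difference in nutrients or growth therefore stays open. The design names no group that could account for it, and oxygen, density and passage are not recorded in the labels used here.

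Long transcripts were lower in replicate 2, whose log2 difference from the other libraries had a slope of -0.12 (SE 0.0023) per doubling of exon length over 11467 genes, with a median of -0.21 among the 1147 genes with the longest transcripts and 0.18 among the 1147 with the shortest. Replicate 1 had a slope nearly as large in the opposite direction (0.09, SE 0.0023; medians 0.16 and -0.16), and replicate 3 one of 0.02; since each library was compared with the others, the trend is not assigned to 1 of them. The slope was -0.12 with GC content in the model and -0.094 with genomic span in the model, which argues against GC content or gene body length as the whole cause. After thinning to equal depth it was -0.12. Random thinning leaves the expected CPM of a gene unchanged, so this test cannot decide on depth. Shorter RNA fragments in that library cannot be told apart from other sources of the trend: the slope with genomic span and GC together, -0.10 (SE 0.0030), only restates it, and no measure of fragment length or RNA integrity was used here. No biological explanation was tested.

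Among genes varying between replicates, those with fractional counts, a sign of shared reads, were too frequent but a minority. Of the 76 called genes, 12 had fractional counts (15.8%, exact 95% interval 8.43 to 26.0%), against 3.46% of 11745 other tested genes (Fisher's exact test, two-sided p = 1.3e-05). Sharing of reads between near-identical genes could therefore account for some calls. Most called genes had whole counts, but shared reads given wholly to a single gene would leave no fractions. The share thus does not limit how many calls involve shared reads. Eif3j1 and Eif3j2, chosen after their values were seen, moved in opposite directions (727, 520 and 238 against 1428, 1377 and 2569 counts). In TMM-scaled CPM, Eif3j1 was at 40.5, 37.2 and 15.7 and Eif3j2 at 79.6, 98.5 and 169. The rise in replicate 3 exceeded the fall, so an exchange of reads between these genes alone does not account for it. No biological explanation was tested for the called genes.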

How the results depend on the processing

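Alternatives chosen after seeing the data were the length and GC offset, whole-count genes only, length-matched random lists, protein-coding genes only, and lists without certain members. Detected genes numbered 11576 to 11687 with a replicate left out, and from 10065 (minimum of 5 CPM) to 13539 (at least 1 count) under the other settings. Lists with a median of at least 10 CPM numbered 16, or 15 per kilobase. The contrasts of the cytoskeleton with progenitor genes (7.12 to 7.25 with a replicate left out) and of cell cycle with inhibitor genes (2.27 to 2.44) kept their direction and side of the threshold under every alternative run. The common biological coefficient of variation ranged from 10.9 to 12.6% with a replicate left out, the highest without replicate 2. The 76 varying genes became 116 with a common dispersion (65 shared), 6812 with Poisson noise, and between 36 and 52 with a replicate left out; the length and GC offset gave 89 and whole-count genes 73. List shifts outside the central range numbered 21 with other scalings, 16 with length-matched lists and 17 after trend removal. They were not recomputed with a replicate left out, which leaves only 1 difference.

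For the adrenergic against mesenchymal contrast, detected members only gave -0.74, because undetected mesenchymal genes drop out. Per kilobase it passed (8.56, permutation adjusted p = 0.0261), also without replicate 1 (9.20) or 2 (8.82), not 3 (8.50). Dropping Vim, Fn1 and Tcf4, the top mesenchymal genes, can only widen it (9.37, 0.00579) and decides nothing. The catecholamine against glutamatergic contrast passed with counts per kilobase (7.92) and with the mean over members (3.84), fell to 0.37 with detected members only, and ranged from 8.13 to 8.22 with a replicate left out, as did that against GABAergic genes, which fell to 0.17 with detected members only. That setting leaves 4 of 14 glutamatergic and 2 of 15 GABAergic genes. The cytoskeleton against synaptic contrast passed with detected members only (1.42) and per kilobase (1.33), not with the mean over members (0.48), with a range of 1.15 to 1.33 over left-out replicates. The catecholamine against cholinergic (4.38 to 5.03) and channel (1.51 to 1.79) contrasts did not pass under any alternative run. With a pseudocount of 1 the log2 ratios were 7.15 for Th against Chat, 7.93 for Elavl4 against Rbfox3, 7.71 for Htr3a against Chrm1 and 8.09 for Cdk4 against Cdk6, smaller because the pseudocount adds more to the lower gene. Per kilobase they were -0.49 for Mycn against Myc, 9.74 for Htr3a against Chrm1 and 11.37 for Cdk4 against Cdk6. With a replicate left out the ranges were 8.67 to 9.53 for Th, -5.46 to -4.998 for Slc18a1, -0.29 to -0.10 for Mycn, 9.92 to 10.57 for Elavl4, 7.95 to 8.30 for Htr3a and 10.54 to 10.84 for Cdk4. Of the list levels, 127 stayed within 1 SD and 29 moved, 19 per kilobase. For 189 named genes, 929 values stayed and 16 moved, but leaving out 1 of 3 libraries cannot move these by 1 SD. No paired analysis was possible because there was only 1 group. Depth limits levels under 3 counts, about 0.2 CPM.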

Other observations

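The lists in this part were written after the data were first examined, and the levels of some members had been seen by then. Of the 39 Hox genes listed, 5 were detected, all in the Hoxc cluster on chromosome 15: Hoxc10 (35.4 ± 2.42 CPM), Hoxc9 (26.2 ± 6.81), Hoxc6 (8.58), Hoxc4 (2.69) and Hoxc8 (1.82). None of the 11 Hoxa, 10 Hoxb or 9 Hoxd genes was detected. Several transcription factors known from heart development were present, with 9 of 16 detected: besides Hand2, Tbx2 and Isl1, which also belong to the sympathetic lineage, Tbx20 (174 ± 35.9 CPM), Nkx2-5 (62.8 ± 15.6) and Gata4 (39.4 ± 5.25) were detected, while Tbx5, Gata6 and Mef2c had no counts. Cardiac muscle genes were low, with Actn2 (6.33 CPM) the highest of 16 and Myh6 at 0.

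Lin28a (99.3 CPM), Lin28b (35.2), Dppa2 (69.6 ± 14.3), Klf4 (11.7) and Dppa4 (11.1) were the detected members of a list of 20 pluripotency and germline factors, whereas Pou5f1, Sox2, Zfp42 and Sall4 had no counts and Nanog was at 0.675 CPM. All 5 detected members were lower in replicate 1 (median log2 difference from the other libraries -0.37) and higher in replicate 3 (0.35). Of 25 imprinted genes, 18 were detected. Mest (1556 ± 66.3 CPM), Gnas (1459 ± 58.5), Peg10 (443 ± 56.4), Dlk1 (377 ± 63.2) and Peg3 (287 ± 94.2) were the highest, whereas Igf2 (3.53) and H19 (9.23) were low and Ndn (0.0404) and Plagl1 (0.0427) were near 0. The amino acid response list held 19 detected genes of 20, with Aars (755 CPM), Gars (699), Slc7a5 (642) and Asns (625) the highest.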
